A study of Mus musculus with 7 samples.

How the data were processed

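The library was made from the trigeminal ganglion of wild-type mice at postnatal day 3.5 and holds single cells captured in droplets. The deposited matrix holds UMI counts, whole numbers per gene and barcode, not normalised. The submitters' processing notes name Cell Ranger 3.1.0 and mm10, while per the file headers the matrix was written by Cell Ranger 7.0.1. The versions differ, and whether intronic reads were counted is not given in the sources used here. The molar libraries, 3 controls and 3 Fgfr2 mutants, were not analysed here, so no comparison between genotypes was made.

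Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs, which left 9427 of 13065. Scrublet, in scanpy 1.11.5, called 2 of these doublets, or 0.0212%, at an automatic threshold of 0.540. A caller that marks so few of this many cells has not worked, so doublets are in effect still present, and leaving out the cells in the top 8% of doublet scores was added as an alternative. Counts were scaled to 10000 per cell and logged, and 2000 variable genes were taken after leaving out every gene of the outcome lists, so that none of these shaped the clusters. Genes outside those lists, such as Mki67, Fos, Gh and Acta1, were not left out. Cells were clustered on 30 principal components with 20 neighbours and the Leiden method at resolution 1 (leidenalg 0.10.2, seed 0), which gave 34 clusters. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

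Clusters were named from marker lists fixed before the data were examined, for example Tubb3, Snap25, Prph and Avil for neurons, Fabp7 and Kcnj10 for satellite glia, Prx and Pmp22 for myelinating Schwann cells, Scn7a, Ngfr and Cdh2 for non-myelinating or immature Schwann cells, Col1a1, Dcn and Pdgfra for fibroblasts, and Mrgprd, Trpm8, Mrgpra3, Calca, Tafa4 or Pvalb for neuron subtypes. A cluster took the type whose markers had the highest mean log2 ratio to the other clusters, with a pseudocount of 10 CPM, if that mean was above 0.3 and at least 3 of them had at least 10 CPM and were 2-fold raised. A cluster with a median UMI count under the library median divided by 3 also needed a marker among its top 10 genes. The scoring rule itself was settled after clusters had been seen and went through 3 versions. The changes made the best-scoring type decide, dropped cycling cells as a class, pooled the fibroblast and perineurial lists, and, last, left unnamed a cluster with no marker among its top 10 genes when another type had at least 0.8 times as many raised markers. The last change left unnamed 2 small clusters and a neuron subtype that the version before had named, and that version was run as an alternative. In the end 5 clusters, 843 cells, were unnamed and stayed out of comparisons. Neurons were clustered again alone at resolution 1 and named from the subtype markers.

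UMIs were summed per class and given as CPM, a scaled share of all UMIs of the class, with exact Poisson intervals. Ratios of CPM have exact conditional binomial intervals. Neurons were compared with all other named cells together. A gene counted as higher when it had at least 20 UMIs over both sides, a ratio of at least 2 and an interval above 1, and as lower when the ratio was at most 0.5 with an interval below 1. These counts describe 1 library and are not tests. The position of a list is the percentile of its median log2 ratio, with a pseudocount of 1 CPM, among 10000 random lists of genes from the same of 20 expression bins. The lists were fixed before the data were examined. The genes named were fixed by rule: every FGF and Hedgehog list member with at least 20 UMIs, up to 3 higher and 3 lower genes of each other ligand list, up to 5 leading ligands of each class and the 15 most subtype-restricted ligand genes, of which the text gives a part, and some named genes are not reported here. Comparisons between single classes, the Fgf1, Fgf9 and Mki67 values of glial clusters, the Dhh values of subtypes and the Nrg4, Fos, Npy, Gh and Acta1 values were chosen after their values were seen. For shares of cells with a UMI, cells were thinned to 5000 UMIs.

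Neuron markers in blood and vessel cells stood at 2.45% of their neuronal level (median of 13 markers), a measure of free neuronal RNA in the droplets. Of the 32285 gene identifiers, 32235 were found in the mouse annotation of the same build used for positions. On simulated counts for 19747 genes of the comparison of neurons with other cells, the criterion recovered 94 of 100 genes changed 3-fold and 98 of 100 changed 6-fold, and 0.414% of unchanged genes were counted. These counts were drawn from the Poisson model that the intervals assume, without free RNA, doublets or misnamed cells. They do not give an error rate for the real library. In 2510 cells simulated from the class profiles, without doublets or free RNA, all cells were given their own class; this is an easy case and does not measure naming errors in the real cells.

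Alternatives fixed before the data were examined were other cell filters, doublets kept, other resolutions and numbers of components, UMIs per cell, CPM without mitochondrial, ribosomal protein and haemoglobin genes, the mean of per-cell CPM, equal weight for each class, subtraction of neuron-derived background, and other count minimums. Added after seeing the data were leaving out neurons under 20000 UMIs, glia-like cells alone as the other side, leaving out high doublet scores and the earlier naming rule.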

Results

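The series asks how sensory nerve acts on progenitor cells of the growing tooth root through FGF and Hedgehog signals. The part analysed here is 1 single-cell RNA-seq library of the wild-type mouse trigeminal ganglion, the ganglion that holds the sensory neurons of the face and teeth, taken at postnatal day 3.5. A further 6 bulk libraries of mouse molars at postnatal day 7.5, 3 from controls and 3 from animals with Fgfr2 removed in the Gli1 lineage, are labelled in the series and were not analysed here. The ganglion library held 149040354 UMIs over 13065 barcodes and 32285 genes, with a median of 8152 UMIs per barcode. After filtering, 9425 cells remained, with a median of 10858 UMIs and 3651 genes. With 1 library there is no replicate error, no test was made and no p-value is given. Intervals are exact 95% intervals that cover counting error only.

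Neuron-like cells made up 608 of the 9425 cells, or 6.45% (5.96 to 6.97, Clopper-Pearson), and carried 26.9% of the UMIs of named cells, with a median of 55876.5 UMIs per cell. Glia were the most numerous group, with 1873 myelinating Schwann-like cells, 1603 non-myelinating or immature Schwann-like cells and 344 satellite glia-like cells. Fibroblast- or perineurial-like cells numbered 1620, erythroid-like cells 698 and macrophage-like cells 467. Smaller classes were cartilage- or bone-like (292 cells), central oligodendrocyte lineage-like (290), endothelial-like (277), neutrophil- or monocyte-like (178), B lymphocyte-like (104), mural-like (84), central astrocyte-like (72) and mast cell-like (72). The cartilage or bone, oligodendrocyte and astrocyte classes are of tissues that lie next to the ganglion. The mast cell-like cluster also had platelet genes (Ppbp, Itga2b, Gp9) among its leading genes and 9 raised markers of T or NK lymphocytes. Immune genes (Ccl3, Ccl12, Cxcl2) were among the leading genes of the larger macrophage-like cluster, cell cycle genes led 1 Schwann-like cluster of 345 cells, and a myelinating Schwann-like cluster of 655 cells had a median of only 1927 UMIs. The remaining 843 cells, with a median of 1781 UMIs, were left unnamed. The neuron share depended on the processing, with 12.4% when no cell filter was used and 9.60% when the 2 called doublets were kept. Leaving out neurons under 20000 UMIs, which could only lower the share, gave 4.08%. The share is of sequenced barcodes and depends on which cells survived dissociation.

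The first question was which secreted FGF genes the neurons of the ganglion expressed. Of the 12 secreted FGF genes with at least 20 UMIs, 4 were at least 2-fold higher in neuron-like cells than in all other named cells together, and 4 were at least 2-fold lower. Fgf1, which encodes an FGF that binds all FGF receptors, had 70.4 CPM in neurons (67.7 to 73.2, 2531 UMIs) and 17.3 CPM in other cells (16.5 to 18.2, 1690 UMIs), a ratio of 4.07 (3.82 to 4.33). Fgf18, a ligand with roles in skeletal growth, had 18.6 CPM against 3.37 CPM, a ratio of 5.52 (4.83 to 6.32). Fgf5, known for its part in the hair cycle, reached 8.79 CPM against 0.440 CPM, a ratio of 19.96 (14.5 to 28.1). Fgf22, known as a synapse-organising ligand, reached 4.12 CPM against 0.604 CPM, a ratio of 6.81 (5.01 to 9.38).

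Fgf2 was 10.4-fold lower in neurons, at 1.22 CPM against 12.7 CPM, and Fgf7, a ligand for epithelial receptors, was 6.07-fold lower. Fgf17 and Fgf21 were also lower in neurons, on 2 and 1 neuronal UMIs, with ratios of 0.187 (0.0217 to 0.740) and 0.0512 (0.00127 to 0.298). Fgf9 had a ratio of 0.506 (0.419 to 0.607), just short of the 2-fold limit and turned to 2.44 (2.02 to 2.93) as UMIs per cell, while Fgf10 (0.946, 0.607 to 1.44), Fgf20 (1.20, 0.776 to 1.82) and Fgf23 (0.362, 0.0926 to 1.03) had intervals that included 1. The median log2 ratio of the 12 genes was -0.14, at the 74.9 percentile of 10000 random lists matched on expression, so the list as a whole did not stand apart. This percentile ranged widely, from 53.4 with no minimum count to 95.6 with the classes weighted equally. Counted as UMIs per cell, which keeps the larger RNA content of neurons, 7 genes were at least 2-fold higher and the Fgf1 ratio was 19.6.

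**Figure D1:**
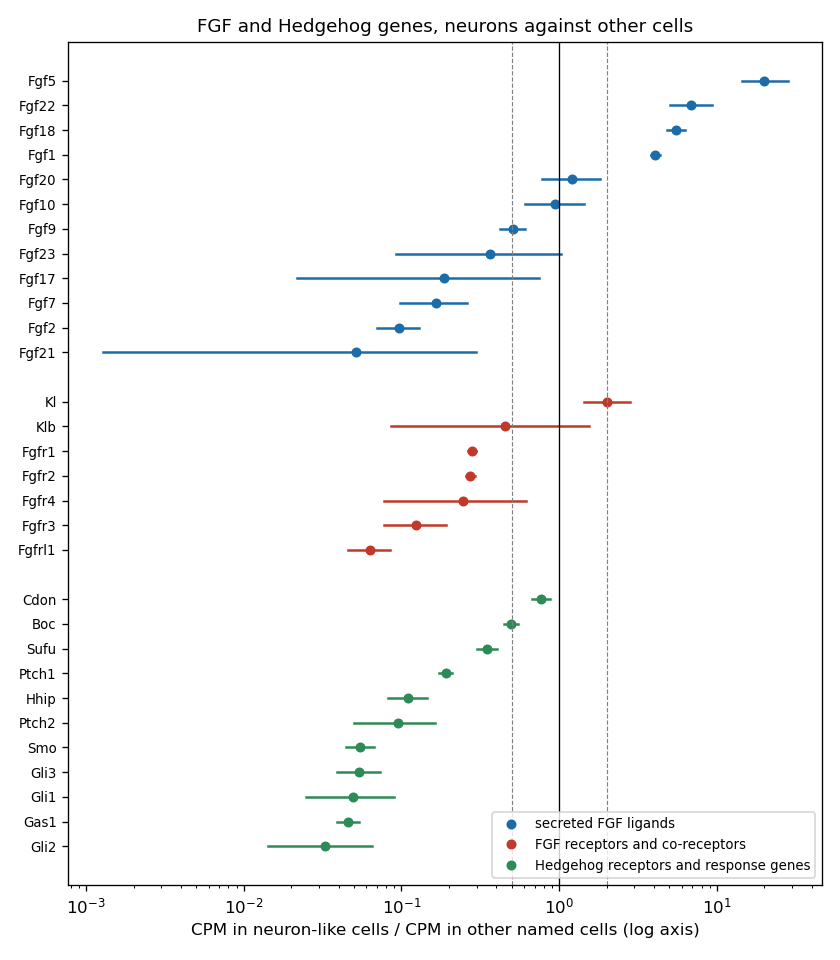
CPM in neuron-like cells divided by CPM in all other named cells (log axis) for each secreted FGF, FGF receptor and Hedgehog receptor or response gene with at least 20 UMIs. Points are ratios, lines are exact 95% counting intervals, the solid line marks 1 and dashed lines mark 2-fold. Of the genes with an interval below 1, Fgf9, Fgfr1, Fgfr2, Boc, Cdon and Sufu turn to ratios above 1 as UMIs per cell. Fgfr4 also passes 1 on that scale, with an interval that includes 1. Fgf5, Fgf22, Fgf18 and Fgf1 lie to the right, from 19.96 down to 4.07.

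Fgf1 was not confined to neurons. Myelinating Schwann-like cells had 46.5 CPM (43.4 to 49.6, 877 UMIs), so that the ratio of neurons to this class was 1.52 (1.40 to 1.64), and its 3 clusters ranged from 32.7 to 75.1 CPM. Non-myelinating or immature Schwann-like cells had 18.8 CPM, satellite glia-like cells 15.3 CPM and erythroid-like cells 3.18 CPM. Against the 3 glia-like classes alone, the neuronal ratio was 2.27. In the unthinned data a UMI of Fgf1 was seen in 58.6% of neuron-like cells, 29.6% of myelinating Schwann-like cells and 2.87% of erythroid-like cells, which should lack it, at median depths of 55876.5, 10603 and 9927.5 UMIs. After thinning every cell to 5000 UMIs the shares were 24.3% (20.5 to 28.5), 19.7% (17.5 to 22.0) and 1.79% (0.898 to 3.18), with 152, 598 and 84 shallower cells left out.

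**Figure D2:**
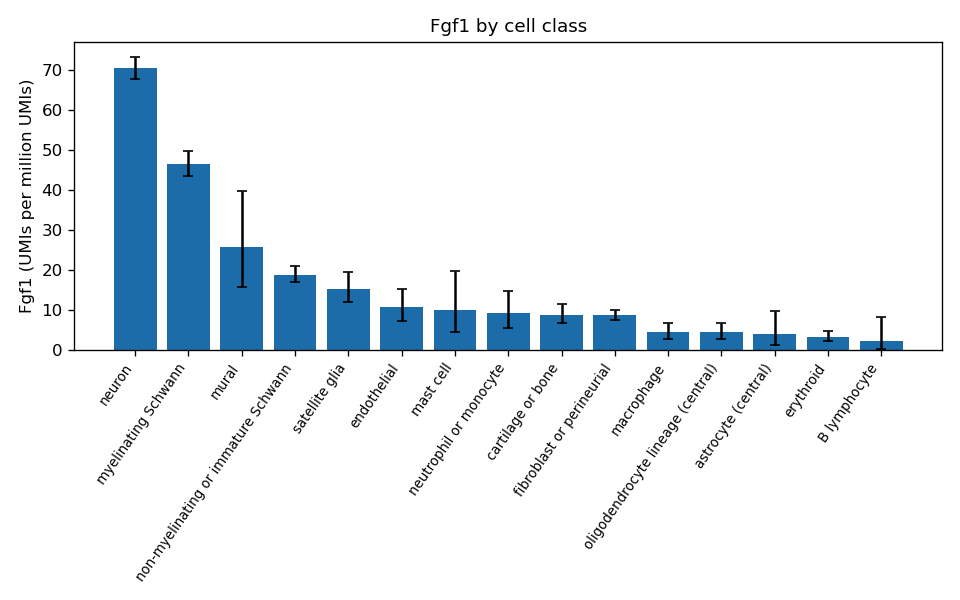
Fgf1 CPM from UMIs summed over the cells of each named class of the 1 ganglion library, with exact 95% Poisson intervals as error bars. Neuron-like cells (70.4) and myelinating Schwann-like cells (46.5) stand above the other classes.

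Fgf9, a ligand active in several organ rudiments, and Fgf2 had their own pattern among glia. In non-myelinating or immature Schwann-like cells Fgf9 had 28.7 CPM, 3.84-fold (3.18 to 4.66) above myelinating Schwann-like cells, whose 3 clusters ranged from 0.712 to 13.4 CPM. Fgf2 was 2.38-fold (2.01 to 2.81) higher in the same comparison. The genomic positions of the neuron-enriched ligands, in mm10, are chromosome 18, 38838673 to 38929472 for Fgf1 (ENSMUSG00000036585), chromosome 11, 33117430 to 33147400 for Fgf18 (ENSMUSG00000057967), chromosome 5, 98254184 to 98277030 for Fgf5 (ENSMUSG00000029337) and chromosome 10, 79755076 to 79758596 for Fgf22 (ENSMUSG00000020327). Fgf1 overlaps Arhgap26 and AC110730.1 and Fgf22 overlaps Rnf126, all on the opposite strand, and Fgf5 and Fgf18 overlap no annotated gene.

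The intracellular FGF homologous factors, which are not secreted and act on sodium channels, were mostly neuronal: 3 of 4 were higher. Fgf13 had a ratio of 30.9 (29.6 to 32.3), Fgf12 of 17.3 (16.4 to 18.2) and Fgf11 of 2.72 (2.13 to 3.47), while Fgf14 had 1.11 (1.02 to 1.21).

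FGF receptors were lower in neurons by CPM, though Fgfr1 and Fgfr2 turned, to ratios of 1.35 and 1.32, when counted as UMIs per cell. On that scale Fgfr4 had a ratio of 1.19 (0.372 to 2.95), with an interval that included 1. Of 7 receptor and co-receptor genes, 5 were at least 2-fold lower, namely Fgfr1 (3.58-fold), Fgfr2 (3.67-fold), Fgfr3 (8.03-fold), Fgfr4 (4.05-fold, on 5 neuronal UMIs) and the decoy receptor Fgfrl1 (15.8-fold). Kl, which encodes the FGF23 co-receptor Klotho, was higher than in other cells together, with a ratio of 2.01 (1.43 to 2.80). Its CPM was higher still in fibroblast- or perineurial-like cells, on 80 UMIs against 65 in neurons. Fgfr1 had 387 CPM in satellite glia-like cells and 242 CPM in fibroblast- or perineurial-like cells, against 30.8 CPM in neurons. Fgfr2 had 161 CPM in fibroblast- or perineurial-like cells and 122 CPM in myelinating Schwann-like cells. Counted as UMIs per cell, 1 of the 7 genes stayed at least 2-fold lower. In mm10, Fgfr1 (ENSMUSG00000031565) lies on chromosome 8, 25513654 to 25575718, and the annotated Fgfr2 gene (ENSMUSG00000030849), chromosome 7 from 130162451 to 133123350, spans many other genes, so its UMIs are less certain.

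Genes of the FGF response list went both ways by CPM, and whether FGF signalling drove them here was not tested. As UMIs per cell, 10 of 13 were at least 2-fold higher in neurons and 1, Spry1, lower, with Etv4, Spry4, Spred1 and Il17rd turned. Of 13 response genes, 3 were higher in neurons than in other cells together (Etv1, 2.33; Spry3, 13.7; Spred3, 2.36), though Etv1 had 116 CPM in fibroblast- or perineurial-like cells against 91.5 CPM in neurons, and 3 were lower (Spry1, 12.9-fold; Dusp4, 9.37-fold; Dusp6, 5.53-fold). Etv5, the FGF-responsive transcription factor named in the series title, had 38.5 CPM in neurons and 24.5 CPM in other cells, a ratio of 1.57 (1.47 to 1.68). Etv5 reached 46.5 CPM in fibroblast- or perineurial-like cells and 64.8 CPM in central astrocyte-like cells. Within neurons, Etv1 had 418 CPM in 29 Mrgpra3-like cells against 59.3 CPM in all other neurons.

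The Hedgehog pathway genes were low in neurons by CPM, though Boc, Cdon and Sufu turned, to 2.41, 3.71 and 1.69, when counted as UMIs per cell. Of 11 receptor and response genes, 10 were at least 2-fold lower, and the list's median log2 ratio of -2.46 lay at the 0.02 percentile of random lists. The receptor gene Ptch1 was 5.26-fold lower, the transducer Smo 18.2-fold, the transcription factor genes Gli1, Gli2 and Gli3 20.1-, 30.3- and 18.5-fold, and the co-receptor Gas1 21.8-fold. Cdon had a ratio of 0.768 (0.676 to 0.872) and was not counted, and Boc was near the limit at 0.498 (0.449 to 0.551). Ptch1 had 183 CPM in fibroblast- or perineurial-like cells, 3.54-fold (3.36 to 3.73) above the glia-like classes, and Gli1 had 20.6 CPM there, 28.2-fold (19.5 to 42.3) above them. Mural-like cells had a similar Gli1 level, 23.1 CPM. Counted as UMIs per cell, 6 of the 11 genes stayed at least 2-fold lower, and Ptch1, at 0.919 (0.840 to 1.00), did not. Against glia-like cells alone, 7 of the 11 genes were at least 2-fold lower by CPM and Boc turned to 3.74. The folds were smaller for some genes there, with Gli1 at 0.728 CPM in glia-like cells and 0.306 CPM in neurons.

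Of the Hedgehog ligands, Shh was seen on 55 UMIs in neurons and 5 in other cells, a ratio of 29.9 (12.1 to 95.6) at a low level of 1.53 CPM. Dhh, the ligand that Schwann cells use to pattern the nerve sheath, was 2.53-fold lower in neurons, at 34.9 CPM (a ratio of 1.91 the other way as UMIs per cell), and had 236 CPM in satellite glia-like and 226 CPM in myelinating Schwann-like cells. Ihh, on 4 and 27 UMIs, had a ratio of 0.402 (0.102 to 1.15). In mm10, Shh (ENSMUSG00000002633) lies on chromosome 5, 28456815 to 28467256, Dhh (ENSMUSG00000023000) on chromosome 15, 98891152 to 98898540, Ptch1 (ENSMUSG00000021466) on chromosome 13, 63508328 to 63573598, and Gli1 (ENSMUSG00000025407) on chromosome 10, 127329882 to 127341974. Dhh overlaps Rhebl1 and Ptch1 overlaps A930032L01Rik on the same strand, so some of their UMIs are uncertain.

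The wider question was which ligand families the neurons expressed. Of 196 ligand genes in 15 lists with at least 20 UMIs, 38 were at least 2-fold higher in neurons and 113 at least 2-fold lower, a split that became 84 to 50 as UMIs per cell and 75 to 51 against glia-like cells alone. Neuropeptides were the most neuronal list, with 14 of 23 higher and 8 lower, and their median log2 ratio of 1.24 lay at the 99.99 percentile of random lists. The vasodilator peptide gene Vip had a ratio of 163 (100.1 to 287), Adcyap1, which encodes PACAP, of 96.8 (81.1 to 116) and the granin gene Scg2 of 64.0 (55.7 to 73.9). Of the neuregulin genes, 3 were higher in neurons by CPM and Nrg4, with a ratio of 1.22 (0.870 to 1.70), was not. Nrg3 had a ratio of 42.3 (39.5 to 45.4), Nrg1 of 18.2 (16.7 to 19.8) and Nrg2 of 7.59 (6.71 to 8.60). Products of Nrg1 are known to act on Schwann cell growth and myelination. Other genes higher in neurons than in other cells together were Sema4f (54.7), Slit1 (14.6), the neurotrophin genes Bdnf (14.5) and Ntf3 (6.23), the Notch ligand genes Jag2 (12.6) and Dll3 (8.49), Efna3 (8.30), Wnt2b (7.51), Inha (5.27), Hgf (3.03), Vegfb (2.85) and Gdf11 (2.59). Some had a higher CPM in a single other class than in neurons. These were Jag2 in endothelial-like, Dll3 in central oligodendrocyte lineage-like, Vegfb in central astrocyte-like and Gdf11 in mural-like cells. Hgf was higher in macrophage-like, mast cell-like and neutrophil- or monocyte-like cells.

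Other lists were mixed, with 2 of 15 WNT ligand genes higher and 10 lower, 3 and 10 of 20 semaphorin genes, 3 and 4 of 10 EGF and neuregulin genes, 2 and 3 of 11 neurotrophin and GDNF family genes, and 2 and 4 of 6 Notch ligand genes. Of TGF-beta and activin genes 1 of 6 was higher and 3 lower, of PDGF, VEGF and angiopoietin genes 1 of 12 and 6, of ephrin genes 1 of 8 and 5, and of slit and netrin genes 1 of 9 and 4. Several families were low in neurons. Chemokines and cytokines had 33 of 37 genes lower and none higher, BMP and GDF ligands 12 of 16 lower, and IGF, HGF, pleiotrophin and midkine ligands 6 of 8 lower, and all 3 lists lay at the 0 percentile of random lists. The BMP and GDF count, and so the total of 196 ligand genes, includes Bmp1 (8.76-fold lower), which encodes a protease and not a ligand. Igf2, a fetal growth factor, had 340 CPM in other cells and 13.6 CPM in neurons, and the heparin-binding growth factor gene Mdk had 533 CPM and 34.5 CPM. Bmp6 had a ratio of 0.0431 (0.0326 to 0.0559) and Tgfb1 of 0.0657. Genes with no UMI in neurons are lower bounds against a floor of 3 counts: Cxcl9 was at least 13.0-fold lower and Wnt7b at least 10.7-fold lower. Against glia-like cells alone, Bmp6, Igf2, Penk, Sema3a and Boc turned among the named genes past 2-fold by CPM, to ratios of 1.63, 1.09, 4.79, 1.48 and 3.74. Genes outside the named ones were not followed, and others turned as well. Igf1, for example, had 67, 80 and 25 UMIs in myelinating Schwann-like, non-myelinating or immature Schwann-like and satellite glia-like cells, against 1042 in neurons.

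**Figure D3:**
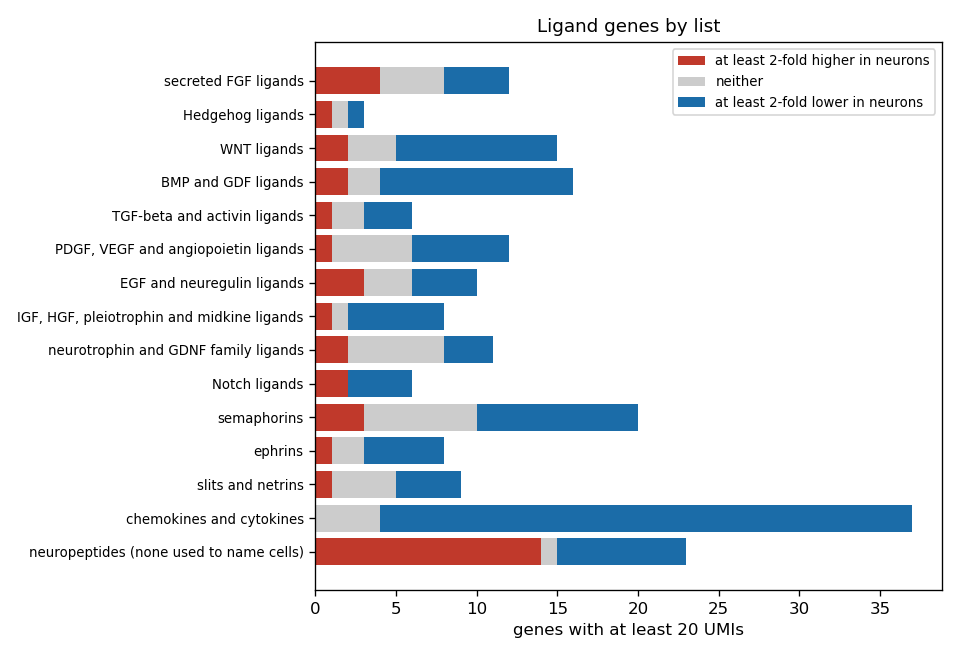
Number of ligand genes with at least 20 UMIs in each of the 15 fixed lists, split by whether CPM was at least 2-fold higher in neuron-like cells (red), at least 2-fold lower (blue) or neither (grey). Neuropeptides have 14 genes in red, and chemokines and cytokines have 33 in blue; as UMIs per cell the split over all lists is 84 higher to 50 lower.

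The non-neuronal classes were raised in different ligands, some shared between classes and given as CPM ratios to all other named cells. Macrophage-like cells were raised in chemokines, with Ccl24 at 649 (465 to 933), Ccl12 at 288 and Ccl3 at 209. Endothelial-like cells were raised in the Notch ligand gene Dll4 (173) and the vasoconstrictor gene Edn1 (78.6). Fibroblast- or perineurial-like cells were raised in the eosinophil chemokine gene Ccl11 (71.1), the enkephalin precursor gene Penk (70.4), Edn3 (64.6), Gdf10 (48.6) and Bmp6 (46.3). Myelinating Schwann-like cells were raised in Il16 (13.5), level with B lymphocyte-like cells at 71.2 and 71.7 CPM, and in Cntf (7.04), which was higher still in central astrocyte-like cells (14.4); Cntf overlaps Zfp91 on its own strand, so which gene its UMIs come from is uncertain. Satellite glia-like cells were raised in the placental growth factor gene Pgf (9.25) and Jag1 (8.60), and non-myelinating or immature Schwann-like cells in Fgf9 (9.02) and Wnt6 (8.09). Cartilage- or bone-like cells were raised in Wnt10b (92.9, on 32 UMIs) and Bmp3 (41.1), and central oligodendrocyte lineage-like cells in Tgfa (21.0) and in Wnt3 (28.4), which was higher still in central astrocyte-like cells (35.4).

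Neurons clustered alone gave 6 named subtypes: 100 Mrgprd non-peptidergic nociceptor-like, 82 peptidergic nociceptor-like, 49 large myelinated A-fibre-like, 44 C-low-threshold mechanoreceptor-like, 31 Trpm8 cold-sensing-like and 29 Mrgpra3 pruriceptor-like cells. The other 273 neurons, with a median of 4781 UMIs, stayed unnamed. Of the secreted FGF genes, 5 were at least 2-fold higher in some subtype than in all other neurons. A-fibre-like neurons had the most of these, with Fgf10 at 6.31 CPM (ratio 40.2, 15.2 to 133.9, on 26 UMIs), Fgf9 at 19.9 CPM (ratio 11.3, 7.95 to 16.2) and Fgf18 at 38.1 CPM (ratio 2.37, 1.97 to 2.84). Fgf22 was higher in Trpm8-like neurons, at 16.3 CPM (ratio 4.98, 3.35 to 7.26). Fgf5 was higher in C-low-threshold mechanoreceptor-like (ratio 2.02, 1.47 to 2.72) and Mrgprd-like neurons (ratio 2.04, 1.62 to 2.55). Fgf1 reached no 2-fold excess in any subtype and was low in Trpm8-like neurons, at 3.00 CPM (1.21 to 6.18, 7 UMIs), against 39.8 to 122 CPM in the other 5 subtypes.

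**Figure D4:**
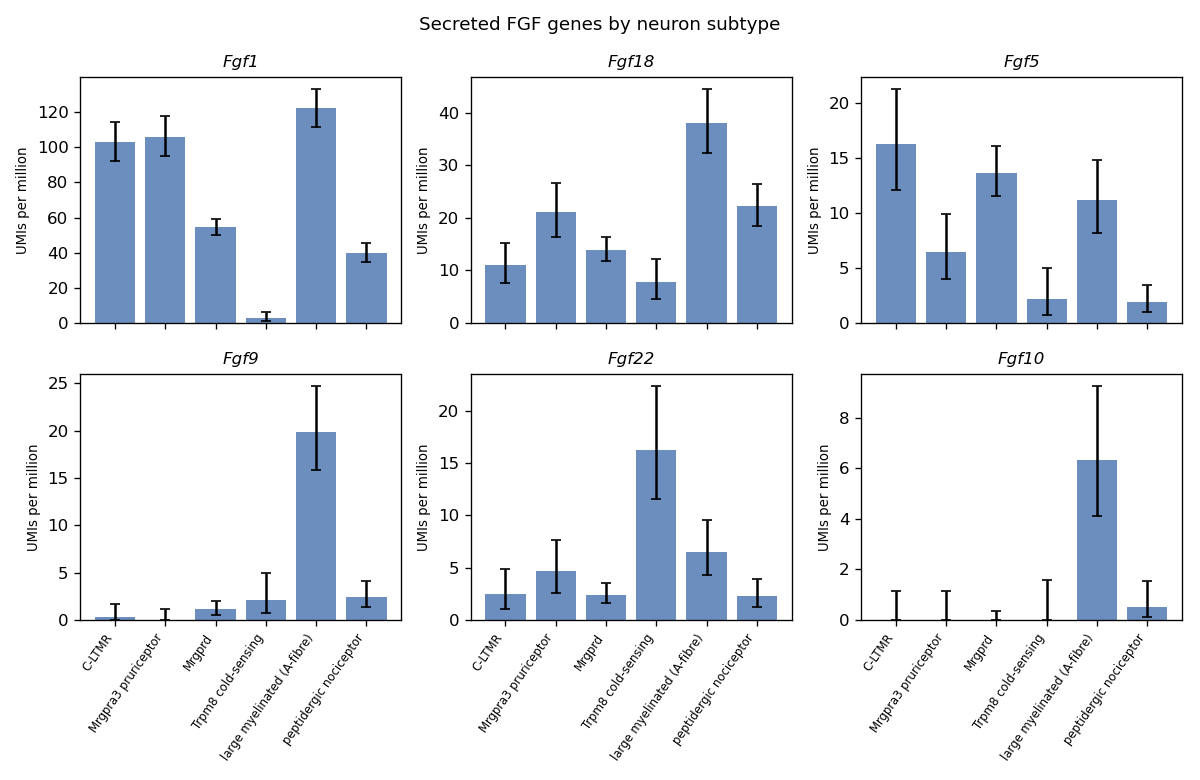
CPM of 6 secreted FGF genes in each named neuron subtype of the 1 ganglion library, with exact 95% Poisson intervals as error bars (C-LTMR stands for C-low-threshold mechanoreceptor). Fgf1 is at 3.00 in Trpm8-like neurons, and Fgf9 and Fgf10 are highest in A-fibre-like neurons, at 19.9 and 6.31.

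Among all ligand genes, peptidergic nociceptor-like neurons stood out in Vip (ratio 1031, 440 to 3183, 958 against 5 UMIs), Gal (15.7, 14.8 to 16.7), Adcyap1 (13.8, 12.9 to 14.7) and Cartpt (13.0, 11.3 to 15.1), all genes of neuropeptides, and in Inhba (21.5), Ntn1 (16.1) and Bmp3 (13.5). A-fibre-like neurons stood out in the membrane-bound netrin genes Ntng1 (28.0) and Ntng2 (15.2), in Tac2 (23.5), the GDNF family gene Nrtn (18.9), Sema7a (14.6) and Shh (13.5, 7.59 to 24.7, 35 of the 55 neuronal UMIs). Trpm8-like neurons stood out in Angpt4 (70.0, 30.6 to 187, 34 UMIs). Dhh had 119 CPM in C-low-threshold mechanoreceptor-like neurons, 4.49-fold (3.97 to 5.07) above other neurons. It was also seen in Mrgprd-like neurons, at 51.1 CPM with more UMIs (545 against 382), and in Mrgpra3-like neurons at 30.7 CPM, against 3.15 to 4.97 CPM in the other 3 subtypes. These subtypes rest on 29 to 100 cells of 1 library.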

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

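Signals in barcodes that no comparison used were looked for against a floor of 3 counts. The 843 unnamed cells had 725 CPM of Gh, the growth hormone gene of the pituitary (701 to 750, 3416 UMIs), where that floor is 0.637 CPM and named cells had 1.20 CPM. These UMIs came from 2 of the 5 unnamed clusters, of 518 and 207 cells, at 870 and 921 CPM, and the other 3 had 0. In the cluster of 207 cells Otor, Dcc and Barhl1 ranked ahead of Gh among the leading genes. It had 2 raised pituitary markers, short of the 3 needed for a name. The unnamed cells also had 25.5 CPM of Acta1, the skeletal muscle actin gene (21.1 to 30.5, 120 UMIs), against 3.84 CPM in named cells, with 111 of these UMIs in the cluster of 518 cells, at 88.0 CPM, and 3.18 CPM in the cluster of 207 cells. The cluster of 518 cells also held neuronal RNA, with 1711 CPM of Prph, against 1459 CPM in named cells. In the 3638 barcodes removed by the filter, haemoglobin genes took 73.0% of UMIs, against 4.37% in named cells.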

How the results depend on the processing

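No paired analysis was possible because the ganglion is 1 library and the molar libraries were not analysed here. Under all 18 alternatives, 14 planned and 4 chosen after seeing the data, Fgf1, Fgf5, Fgf18 and Fgf22 were at least 2-fold higher in neurons. The count minimums leave these ratios unchanged. UMIs per cell and background subtraction can only raise them, so these settings could not change this. The neuron share was 5.90% with at least 1000 genes, 12.4% with no cell filter, 9.60% with doublets kept and 9.94% at resolution 0.5. It was 5.70% with 50 components and 12% without the top 8% of doublet scores, so this share is not firm. The cause was not tested. Leaving out neurons under 20000 UMIs could only lower the share, and gave 4.08%. The Fgf1 ratio was 4.33 at resolution 2, 3.61 without mitochondrial, ribosomal protein and haemoglobin genes, 2.87 as a mean of per-cell CPM, 5.75 with classes weighted equally, 4.52 with background subtracted, 2.27 against glia-like cells and 19.6 as UMIs per cell. With UMIs per cell, 84 ligand genes were higher and 50 lower, 7 secreted FGF genes were higher, and 1 receptor and 6 Hedgehog genes were lower. Of the named genes past 2-fold by CPM, Boc (2.41), Dhh (1.91), Efnb1 (1.61), Fgfr1 (1.35), Fgfr2 (1.32), Fgfr4 (1.19, 0.372 to 2.95), Sufu (1.69), Tgfa (1.62) and Tgfb2 (1.06) reversed. In the FGF and Hedgehog lists, Fgf9 (2.44), Cdon (3.71), Etv4 (3.73), Spry4 (3.20), Spred1 (3.31) and Il17rd (2.95) also turned, from CPM ratios short of 2-fold with intervals below 1. This scale multiplies every ratio by the greater UMI number of neurons. It therefore also turned ligand genes that were not followed, such as Efna5 and Efnb2. Against glia-like cells alone, 75 ligand genes were higher and 51 lower. Of the named genes past 2-fold by CPM, Bmp6 (1.63), Boc (3.74), Igf2 (1.09), Penk (4.79) and Sema3a (1.48) reversed. Genes outside the named ones also turned but were not followed, and the cause was not tested. Wnt7a fell to 0.856 with classes weighted equally, Ntn4 in erythroid-like cells to 0.830 with no cell filter and Cxcl14 in B lymphocyte-like cells to 0 without the top doublet scores; the cause was not tested. With no minimum count, 8 secreted FGF genes were higher in a neuron subtype. The percentile of the secreted FGF list was 74 at 10% mitochondrial UMIs, 72.4 and 71.4 at resolutions 0.5 and 2, 76.8 with 50 components, 76.9 without top doublet scores, 73.7 with the earlier naming rule, 76.7 as UMIs per cell, 70.2 as mean per-cell CPM, 95.6 with equal weights, 73.4 with background subtracted, 91.6 at a minimum of 100 UMIs, 53.4 with no minimum, 72.2 without shallow neurons and 79.1 against glia-like cells; the cause was not tested. Of 2710 alternative values of named genes, 2224 stayed within the main interval, 469 moved and 17 reversed. Those that stayed include 94 and 111 values under the 2 count minimums, which leave every ratio unchanged and so could not move. Neurons under 20000 UMIs held 1183517 of 35949406 neuronal UMIs, and leaving them out moved 0 of 111 values.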

Other observations

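Proliferation genes differed between the classes of the ganglion. The median of 8 cell cycle genes was 261 CPM in non-myelinating or immature Schwann-like cells, 205 CPM in erythroid-like cells, 183 CPM in B lymphocyte-like cells, 113 to 124 CPM in neutrophil- or monocyte-like, mast cell-like and endothelial-like cells and 102 CPM in satellite glia-like cells, against 17.0 CPM in myelinating Schwann-like cells and 6.72 CPM in neurons. Mki67, a proliferation marker, had 596 CPM (576 to 618) in 1 Schwann-like cluster of 345 cells, which cell cycle genes also define. The other 1258 non-myelinating or immature Schwann-like cells had 45.9 CPM of Mki67, below satellite glia-like cells at 69.8 CPM and a myelinating Schwann-like cluster of 655 cells at 98.4 CPM. The immediate early gene Fos, which tissue dissociation is known to induce, had 3690 CPM in central astrocyte-like, 2885 CPM in satellite glia-like and 2550 CPM in fibroblast- or perineurial-like cells, against 186 CPM in neurons. An unnamed cluster of 29 cells had 2448 CPM of the neuropeptide gene Npy (2253 to 2654), against 2.62 CPM in non-neuronal named cells.

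Of the tests below, those on Fgf1, on Malat1, on the haemoglobin share and on glial RNA for Dhh were chosen after the result was seen, and the groups compared for the low-UMI neurons were also settled after their values had been seen. No biological explanation was tested, since the series has 1 ganglion group.

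Myelinating Schwann-like cells had Fgf1 at 66.0% of the neuronal level, with 32.7 to 75.1 CPM over their 3 clusters. Free neuronal RNA would bring neuron markers along, but these stood at a median of 1.91% of their neuronal level, and Fgf1 was 34.5 times what that share would give. Doublets of neurons and Schwann cells would do the same, and the marker share was 0.029 of the Fgf1 share. Both explanations are argued against, and expression of Fgf1 by these cells may be the source, as a hypothesis.

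A second pattern was a set of neuron-like cells with few UMIs, and in the 2 neuron clusters of low depth (247 cells) 7 nuclear RNAs had a median ratio of 0.37 to the deep neuron clusters (though Neat1 had 2.53) and Malat1 a ratio of 0.329, with 0.199 and 0.210 in their 195 cells under 20000 UMIs and 0.443 and 0.392 in the other 52, which held most of the UMIs. Picked as single neurons under 20000 UMIs (233 cells) the ratios were 1.80 and 2.41, sums carried by 38 shallow cells of the deep clusters (4.84 and 7.17), while the median Malat1 per cell was 713 CPM against 3429 CPM in deep neurons. Cell fragments without a nucleus were therefore not decided for the set: the low clusters are in line with them except for Neat1, and the 38 cells are against. The nuclear RNA and Malat1 ratios were of CPM without haemoglobin genes, so dilution by free haemoglobin RNA could not have lowered them. The haemoglobin share, at most 3.95% of UMIs by any of these choices, therefore decides nothing about these ratios. Empty droplets with free RNA stay open, since neuron markers were 2.35 times the level of unnamed low-UMI cells, between the limits of 2 and 3 set beforehand, and the largest cluster of those cells held neuronal RNA itself (1711 CPM of Prph).

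Dhh, a ligand of glia, was 4.49-fold higher in C-low-threshold mechanoreceptor-like neurons than in other neurons. Mrgprd-like neurons, at 51.1 CPM, are part of those other neurons. Glial RNA from attached glia or doublets would raise glial markers too, but their median ratio was 0.665, or 0.148 of the Dhh ratio. Reads of Rhebl1, which overlaps Dhh on its strand, had a ratio of 1.23, or 0.273 of the Dhh ratio. Expression of Dhh by these neurons may be the source, a hypothesis that rests on 44 cells of 1 library.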
